A study of Drosophila melanogaster with 4 samples.

How the data were processed

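Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map dimethylated lysine on histone H3 (H3K79me2) in nuclei from heads of wild-type Oregon-R adult flies. Per the labels' protocols, flies were grown in population cages over a cycle of 22 days, heads were separated from whole adults with sieves, the tissue was homogenized and fixed with formaldehyde, chromatin was sonicated in SDS, and the antibody complexes were collected on PAS beads. The series holds 4 samples, which are 2 ChIP libraries and 2 input libraries, and each ChIP library has 1 input library of its own. The stage is given as mixed adult, and the sexes are not given.

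Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The deposited lists are on FlyBase release 5, per the file headers. The authors deposited 1 list of regions per ChIP replicate and 1 combined list for the series. Each line gives the first and last base of a region, counted from 1, whether it was called enriched or depleted, and a score. The region caller, its thresholds, the way in which input was used and the way in which the replicates were combined are not given in the sources used here. The deposited score has no stated scale or log base. Every region called enriched had a score above 0 and every region called depleted a score below 0. The authors' score was used to describe, rank or filter regions within a list, and between lists only as ranks. No read counts or coverage were analysed here, so the sequencing depth is unknown and no interval that needs it is given. The confidence intervals on shares of clusters cover counting error over clusters only, and neighbouring clusters are not independent.

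Regions called enriched are termed clusters. Covered shares were computed over the 6 main arms (X, 2L, 2R, 3L, 3R and 4), with lengths from the file headers. Full lengths were used, and no sequence was left out where reads cannot be placed uniquely. X, 2L, 2R, 3L and 3R are termed the large arms. The overlap of the replicates was tested against 1000 circular shifts of one list along each arm, a one-sided permutation test that keeps cluster widths and spacing. The smallest p that these shifts can give is 0.001. In a test on simulated data, 1 of 40 pairs of unrelated lists with the replicates' cluster widths had a p under 0.05, and 20 of 20 pairs did in which 1 list held 50% of the regions of the other. The simulated clusters lay at random positions on each arm, without the uneven density of the deposited lists. The simulation therefore does not give the error rate for these lists. With them, a small p may reflect shared density along the arms as well as shared cluster positions. Values over the 2 ChIP replicates are given as mean ± SD. No p is given for differences in coverage or score between arms. Scores on X were compared with those on the large autosomal arms by width class and in SDs of those 4 arms, which are a yardstick and no error, since the arms of one library are not replicates of each other. Nothing in the labels says whether the replicates came from separate collections of flies, so the spread between them may be technical.

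Regions to name were chosen by a rule fixed before the data were examined. The rule took the 10 widest clusters of the combined list that were at least 50% covered in both replicates, the 5 combined clusters with the highest scores, and the 5 widest clusters of each replicate with no base in the other replicate's list. Stretches without clusters, 1-Mb windows and the 1 Mb next to the centromere were chosen after seeing the data. Also fixed beforehand were 21 gene lists, among them markers of neurons, glia, photoreceptors, muscle, fat body, hemocytes, testis and ovary. The gene table used here is of release 6, whose coordinates differ from those of release 5, so it gave no gene positions. Gene lists were therefore not tested, and regions are named by release 5 coordinates.

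Alternatives were the clusters at or above the median score of each list, joining of clusters under 1 kb apart, removal of clusters under 1 kb, stricter overlap rules, other sets of arms and each replicate alone. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.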

Results

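H3K79me2 is a histone modification placed by the Dot1 methyltransferase, called grappa in flies, and is found over transcribed genes. It was mapped in head nuclei of adult Drosophila melanogaster with 2 ChIP replicates, each with an input library of its own and a list of called regions. Replicate 1 held 6376 enriched clusters and replicate 2 held 10183. The authors' combined list held 9950.

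H3K79me2 clusters occupied a large part of the main arms in each replicate. Replicate 1 covered 32.6 Mb, or 27.1% of the main arms, and replicate 2 covered 36.1 Mb, or 30.0% (28.6% ± 2.07, SD, n = 2). The clusters were broad. The median width was 3413 bp in replicate 1 and 2518.5 bp in replicate 2, and the widest cluster of each was 99747 bp and 59368 bp. Replicate 2 held 1.60 times as many clusters as replicate 1, while clusters of 10 kb or wider numbered 649 in replicate 1 and 376 in replicate 2. Of the 649 wide clusters of replicate 1, 502 (77.3%) were met by at least 2 clusters of replicate 2, though no shifted value of this share was computed. With clusters under 1 kb apart joined, replicate 1 held 4628 clusters and replicate 2 held 7233. The number of clusters thus differed more between the replicates than the length that they covered.

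The first question was whether the same chromatin was marked in both replicates. The replicates shared 24.1 Mb, which was 74.0% of the length covered in replicate 1 and 66.8% of that in replicate 2. Of the length covered in either, 54.1% was shared, against a mean of 16.8% and a highest value of 20.1% over 1000 circular shifts (one-sided permutation test, p = 0.001, the smallest that the shifts can give). A cluster of replicate 1 met one of replicate 2 by at least 1 bp in 88.1% of cases, against 50.3% with shifts. A cluster of replicate 2 met one of replicate 1 in 66.0% of cases, against 38.5% with shifts (p = 0.001 for each, permutation test). On X, 2L, 2R, 3L and 3R, the shared part was between 50.5% (2L) and 56.2% (3R) of the length covered in either replicate. On chromosome 4 it was 8.72%, where the unequal coverage of the replicates limits it. There, 50.9% of the length covered in replicate 2 was shared, against 64.4% to 69.0% on the large arms, and 9.52% of that in replicate 1.

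The clusters with the highest scores were found again most often. In the highest quartile of replicate 1 by the authors' score, 94.1% of clusters (95% Wilson interval 92.8 to 95.1) were at least 50% covered in replicate 2. In the lowest quartile, 63.7% were (61.3 to 66.0). In replicate 2 the highest quartile reached 95.5% (94.6 to 96.2), the third 66.5%, the second 39.0% and the lowest quartile 39.1% (37.3 to 41.1). The second quartile of replicate 2 was thus found again no more often than the lowest. Circular shifts gave means between 27.3% and 31.2% for these quartiles, so the weakest clusters of both replicates also coincided more often than shifted ones (p = 0.001 for each quartile, one-sided permutation test). Clusters with high scores were also wider, with a median of 6530 bp in the highest quartile of replicate 1 and 1823 bp in the lowest. Over the 5586 clusters of replicate 1 with a match, the score correlated with the highest matching score of replicate 2 (Spearman's rho = 0.64). This correlation is across clusters, which are not independent replicates. Width rose with score in both lists (Spearman's rho = 0.76 and 0.79), and a wide cluster can meet more clusters of replicate 2. Taking the highest match may therefore raise the correlation, and no shifted value of it was computed.

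**Figure D1:**
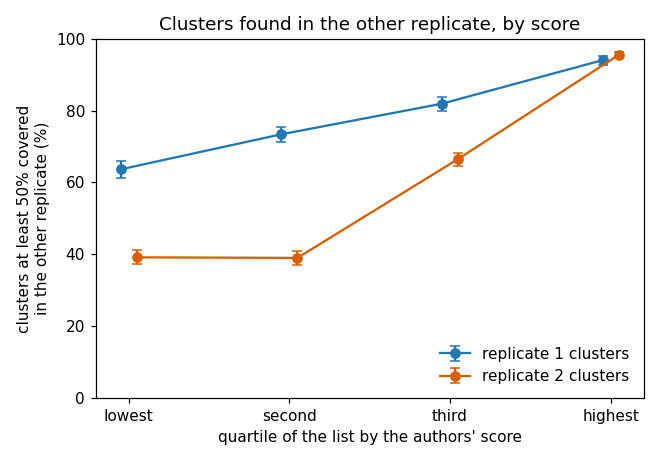
Share of clusters (%) that were at least 50% covered in the other replicate, by quartile of each list on the authors' score, with 95% Wilson intervals as error bars. The share was 63.7% in the lowest and 94.1% in the highest quartile of replicate 1, and 39.1% and 95.5% in those of replicate 2.

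The combined list covered 41.0 Mb, or 34.1% of the main arms. Of this length, 58.8% was covered in both replicates, 12.5% in replicate 1 alone, 24.9% in replicate 2 alone and 3.74% in neither. Of the length shared by the replicates, all but 7140 bp was in the combined list. The combined list also held 89.7% of the length covered in replicate 1 and 95.04% of that in replicate 2. It was made from the same libraries and is no independent evidence.

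Cluster coverage was similar on the large arms and low on chromosome 4, a small chromosome rich in heterochromatin. The covered share was 31.9% ± 3.68 on 2R, 31.3% ± 3.28 on 3R, 28.3% ± 1.33 on 3L, 26.5% ± 2.39 on X and 25.7% ± 0.16 on 2L (SD, n = 2). On chromosome 4 it was 12.6% in replicate 1 and 2.36% in replicate 2, with 52 and 14 clusters. Relative to the large autosomal arms, chromosome 4 was covered 0.45 times as much in replicate 1 and 0.077 times in replicate 2. It thus lay below every large arm in both replicates, while its level depended on the replicate. The assembled heterochromatic pieces of chromosomes 2 and 3 held 30 clusters in replicate 1 and 5 in replicate 2, covering 0.81% and 0.12% of their 8.73 Mb. The X and Y heterochromatin and the unplaced sequences of U held 8 clusters in replicate 1 and 22 in replicate 2, covering 0.16% and 0.44% of 10.6 Mb. No cluster was called on Uextra in any of the 3 lists. Whether reads could be placed uniquely on chromosome 4 and on these sequences was not examined. Low coverage there can therefore not be told apart from sequence in which no call was possible.

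**Figure D2:**
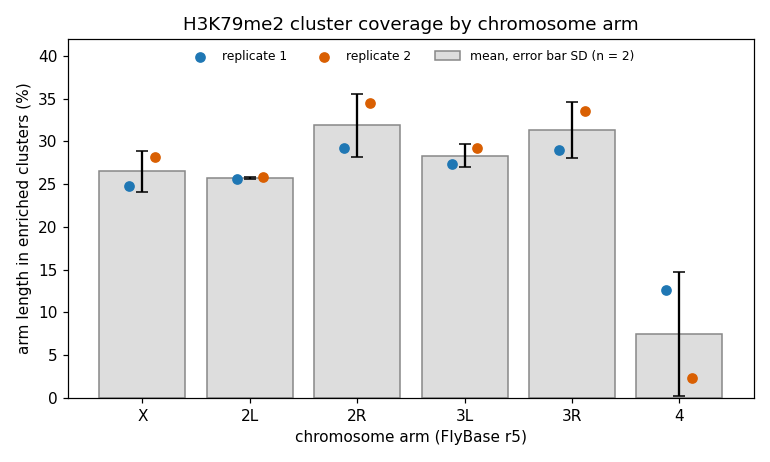
Percent of the length of each main chromosome arm in enriched clusters, with each replicate as a point, their mean as a bar and the SD (n = 2) as the error bar. Chromosome 4 was covered to 12.6% and 2.36%, against 24.8% to 34.5% on the large arms.

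The X chromosome, which is dosage compensated in male flies, was covered slightly less than the pooled large autosomal arms, though in the mean more than 2L, and its clusters scored higher. Its covered share was 0.89 times that of the large autosomal arms in replicate 1 and 0.91 times in replicate 2 (0.90 ± 0.016, SD, n = 2). Among clusters at or above the median score of their list, the ratio was 0.99 in replicate 1 and 1.08 in replicate 2, but this filter favours X, whose clusters score higher. The median score on X was 0.89 in replicate 1, against 0.77 to 0.81 on the 4 large autosomal arms. In replicate 2 it was 0.92, against 0.70 to 0.79. X held 20.0% of the large-arm clusters of replicate 1 and 22.9% of the highest-scoring 5% (95% Wilson interval 18.6 to 27.9, which includes 20.0). In replicate 2 it held 17.3% of the clusters and 24.9% of the highest-scoring 5% (21.3 to 28.8). No p is given for these differences between arms.

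Coverage varied along the arms in a similar way in both replicates. Over 117 windows of 1 Mb on the large arms, the covered shares of the replicates correlated (Pearson's r = 0.86, Spearman's rho = 0.84). Within single arms r was between 0.85 (2R) and 0.88 (3L), and rho between 0.73 (2R) and 0.89 (3L). Windows are neighbours on a chromosome and are not independent. By the mean of the replicates, the densest window was 3R from 5000001 to 6000000, covered to 53.5% in replicate 1 and 49.1% in replicate 2. X from 1000001 to 2000000 was covered to 44.3% and 57.6%, which was above that window in replicate 2. The sparsest by the mean was 3L from 23000001 to 24000000, covered to 1.75% and 0%.

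The 3 sparsest windows lay at the centromeric ends of 3L, 2R and 2L, where the arms pass into pericentric heterochromatin, and the next 2 lay within 2L, from 17000001 and from 15000001. In the 1 Mb nearest the centromere, the covered share was 0.48% ± 0.68 on 3L, 2.45% ± 2.70 on 2R, 3.15% ± 1.19 on 2L and 8.66% ± 2.28 on X, against 26.7% to 33.3% over the rest of these arms (SD, n = 2). On 3R the first 1 Mb was covered to 24.7% ± 2.86, against 31.5% ± 3.29 over the rest, so a drop of that size was not seen there. How much of the sequence near the centromeres allows a call was not examined, so low coverage there need not mean little mark.

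**Figure D3:**
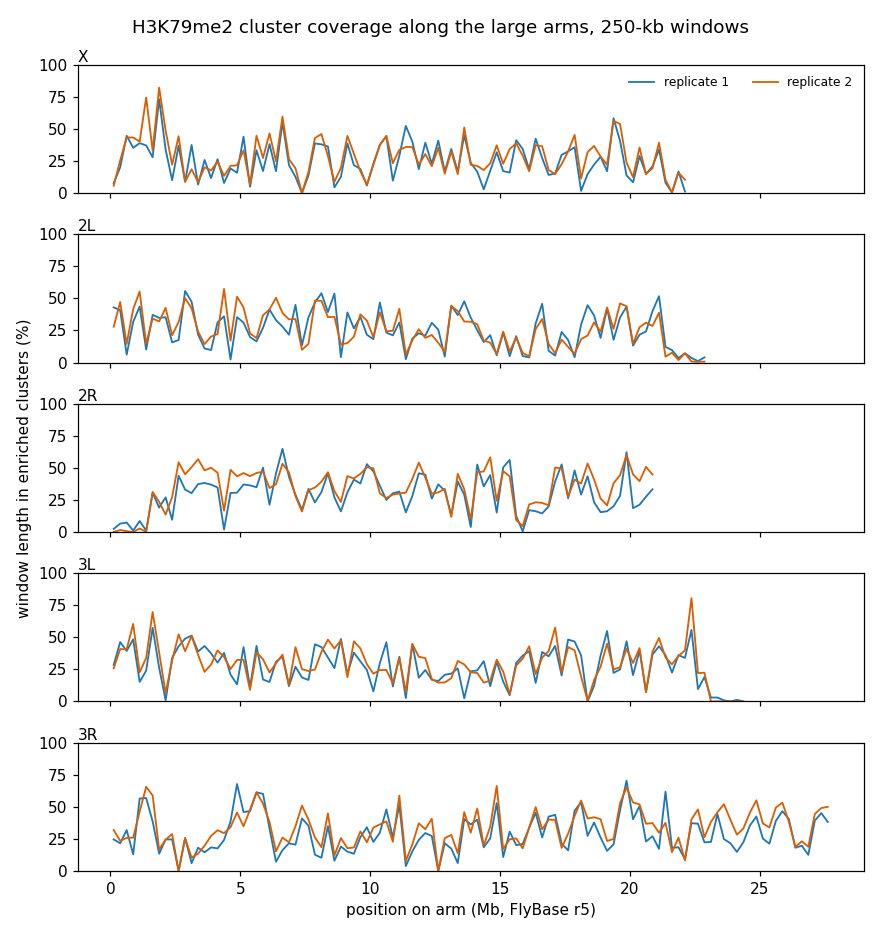
Percent of each 250-kb window in enriched clusters along the 5 large arms (x axis, Mb of FlyBase release 5), 1 line per replicate. Coverage falls toward 0 at the right end of 2L and 3L and the left end of 2R, and within 3R at the stretches near 2.49 and 12.5 Mb.

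Long stretches without H3K79me2 clusters were also found away from the centromeres. On the large arms, centromeric ends included, 88 stretches of at least 100 kb, 14.4 Mb in all, held no cluster in either replicate. The median stretch was 2.19 kb. Within 3R, 404 kb from 2485901 to 2889996 and 330 kb from 12480905 to 12810827 were free of clusters in both replicates. On 3L, 309 kb from 18172206 to 18480705 was free in both, and on X, 285 kb from 7221365 to 7506570, though the combined list covered 0.34% and 0.39% of these 2 stretches. The longest stretch was 506 kb on 3L, from 24024915 to 24530415, at the centromeric end. The 20 longest stretches of replicate 1, 6.35 Mb in all, were covered to 1.95% in replicate 2, against a mean of 30.3% and a lowest value of 18.4% over circular shifts (one-sided permutation test, p = 0.001). This test did not separate stretches at the centromeric ends from those within the arms. Sequence in which no call is possible would be empty in both replicates and was not left out. The test therefore shows that the empty calls coincided, and not that the mark was absent.

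Single marked domains were far wider than the median cluster. The widest domain of the combined list lay on 3L from 17955295 to 18041176, 85.9 kb long. It was 1 cluster in replicate 1, covering 100% of it, and 13 clusters in replicate 2, covering 71.0%. It lay 131 kb from the cluster-free stretch of 309 kb on the same arm. The next widest clusters by the rule were 62.2 kb on 2L from 7893338 to 7955570 and 60.3 kb on X from 1462616 to 1522920. The latter was 83.8% covered by 4 clusters of replicate 1 and 98.4% covered by 1 cluster of replicate 2, so splitting went both ways. The 10 widest were between 41.7 kb and 85.9 kb long, 3 of them lay on X, and each was at least 72.4% covered in replicate 1 and 71.0% in replicate 2.

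**Figure D4:**
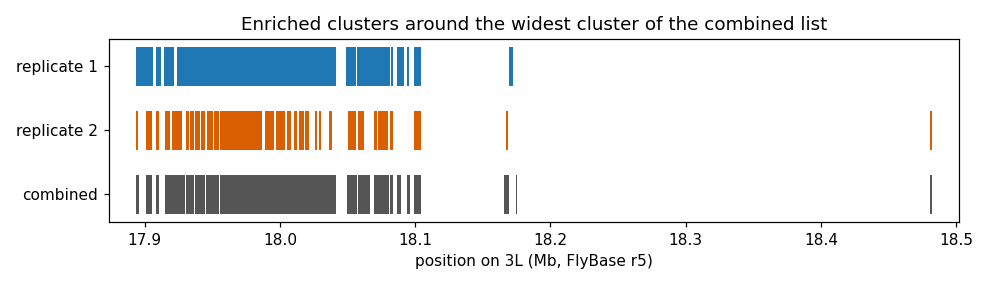
Enriched clusters (filled blocks) of both replicates and of the combined list around this domain on 3L, to scale (x axis, FlyBase release 5). The widest combined cluster, 85.9 kb, is 1 block in replicate 1 and 13 blocks in replicate 2, and the stretch from 18172206 to 18480705 holds no block in either replicate.

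The highest score of the combined list belonged to an 11.9-kb cluster on 3L from 13999637 to 14011536, which was 99.2% covered in replicate 1 and 99.8% in replicate 2. The next was on X from 17553879 to 17564836, 84.6% and 97.0% covered. The remaining clusters among the 5 highest were on 3L from 1772272 to 1794491, on 2R from 16887284 to 16894618 and on 2R from 3269926 to 3277560, each at least 93.9% covered in both replicates.

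Some wide clusters were called in 1 replicate with no base in the other's list. The widest in replicate 1 was 17.4 kb on X, from 581673 to 599098, followed by 16.2 kb on 2L from 7551771 to 7567925 and 11.8 kb on 2L from 18012526 to 18024285. The fourth was on chromosome 4, from 568229 to 578337, and the fifth on 2R, from 8485443 to 8495300. In replicate 2 the widest was 11.3 kb on 2R, from 20103265 to 20114543, and the other four, on 3R, 2L, 3R and 3L, were between 9.94 kb and 10.5 kb. Each was seen in 1 library and has no replicate check.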

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

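Regions called depleted were used in no comparison above and are listed here as a signal outside the main measurement. Replicate 2 held 92 of them, the combined list 11 and replicate 1 none. The tests against chance placement and of the number on X were chosen after the result was seen.

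The depleted regions of replicate 2 were short, from 1447 to 1886 bp, and 69 of the 92 touched an enriched cluster of replicate 1. Circular shifts gave a mean of 31.9 and a highest value of 46 (one-sided permutation test, p = 0.001). More regions thus touched such a cluster than shifts gave. The shifts ran along whole arms, so the excess may reflect shared density along the arms as well as shared positions. In 45 cases the depleted region lay wholly inside the enriched cluster. The touched clusters had a median width of 7.38 kb and a median score at percentile 57.9 of replicate 1. Wide clusters are touched more easily, and the median width of the list was 3413 bp. Width also rose with score in replicate 1 (Spearman's rho = 0.76), so this percentile does not tell whether the touched clusters were weak calls. Short dips between enriched clusters of replicate 2 stay open as a source. A prediction set beforehand was that most of the depleted regions would then lie within 1 kb of such a cluster. It was not met, since 39.1% of them did (95% Wilson interval 29.8 to 49.3). The median distance was 1.22 kb, so the choice of 1 kb as the limit decides the reading. No shifted value of this distance was computed, so the share does not tell whether dips were the main source. A local excess in the input of replicate 2 stays open, since input values were not analysed here, and no biological explanation was tested.

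None of the depleted regions of replicate 2 lay on X, 91 lay on the large autosomal arms and 1 on chromosome 4. X makes up 18.8% of the length of the large arms. A one-sided exact binomial test (p = 5.64e-09) treats regions as independent and restates the count in 1 library that prompted it, so nothing is concluded from it. Of the 11 depleted regions in the combined list, 3 touched one of replicate 2.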

How the results depend on the processing

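A count was taken as moved beyond 1.5 times, a mean beyond 1 SD between the replicates, and a tested overlap when its p passed 0.05, which none did. The values added after seeing the data were the overlap on chromosome 4 alone and the X ratio without the centromere-proximal 1 Mb. Keeping the clusters at or above the median score moved 4 values. By construction it left 3188 clusters in replicate 1 and 5092 in replicate 2, it lowered the mean covered share from 28.6% to 20.6%, and it moved the mean ratio of X to autosomal coverage from 0.90 to 1.03, which crosses equality, though this filter favours X, whose clusters score higher. The shared part of the covered length was 48.4% in those clusters, 54.7% without X and chromosome 4, and 55.2% with clusters under 1 kb apart joined, against shifted means of 11.6% to 17.4%. On chromosome 4 alone it was 8.72%, against a shifted mean of 2.03%, where the unequal coverage of the replicates limits it. With the joining, replicate 1 held 4628 clusters and replicate 2 held 7233, so replicate 2 still held more. Neither replicate list held a cluster under 1 kb, so that filter changed nothing and tests nothing. With a reciprocal overlap of 50%, 53.1% of replicate 1 clusters and 33.1% of replicate 2 clusters had a partner (one-sided permutation test, p = 0.01 for each, the smallest that 99 shifts can give). The ratio of chromosome 4 to autosomal coverage was 0.077 without replicate 1 and 0.45 without replicate 2, so its mean of 0.27 describes neither replicate, and a limit of 1 SD says little there. Among clusters at or above the median score, this ratio was lower, at 0.32 in replicate 1 and 0.050 in replicate 2. A further 8 alternatives set beforehand needed gene positions on release 5 and were not run. No paired analysis was possible because no values of the input samples were analysed, so ChIP and input could not be set against each other by replicate number. Sequencing depth is unknown, and a region outside the lists is one that was not called at this depth.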

Other observations

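Of the tests in this part, those of a looser call in replicate 1 and of a shift shared by heterochromatin, with the grouping of the sequences and the bound used to judge it, and Fisher's exact tests of the cluster numbers against the large arms, which restate those numbers, were chosen after the result was seen, and those of marginal calls and on X were set before.

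Relative to the large arms, where replicate 1 held 6286 clusters and replicate 2 held 10142, replicate 1 held more clusters on chromosome 4 (52 against 14) and on 2LHet, 2RHet, 3LHet and 3RHet together (30 against 5). On the 5 large arms replicate 1 covered at most 0.99 times the share that replicate 2 covered, so it did not cover more everywhere. This does not decide on a looser call in replicate 1, since the covered share also depends on sequencing depth, which is unknown. Marginal calls stay open, as the chromosome 4 clusters of replicate 1 lay at a median percentile of 33.7 of its scores (bootstrap 95% interval 13.4 to 48.7). For a shift of equal size shared by all heterochromatic sequences, a first bound was fewer clusters than the large arms give. It was crossed on none of the 7 sequences other than chromosome 4. XHet, YHet and U held 8 against 22 clusters, 5 and 16 of them on U. This split was not told apart from that of the large arms (two-sided Fisher's exact test, p = 0.26). Chromosome 4 and the 7 other sequences did not split their clusters alike (permutation test, p = 1e-05, the smallest that 100000 permutations can give, with clusters treated as independent). In these lists the split was thus not equal on all heterochromatic sequences. Since this test was chosen after the counts were seen, nothing further is concluded on a shared shift. A shift limited to chromosome 4 and the heterochromatin of chromosomes 2 and 3 stays open, since the counts that raise it cannot also test it. In the 1 Mb nearest the centromere, replicate 1 covered more than replicate 2 on 2L, at 3.99% against 2.31%. The same held on 2R (4.36% against 0.55%) and 3L (0.96% against 0%). Replicate 1 covered less there on 3R (22.7% against 26.8%) and X (7.04% against 10.3%). That stretch was chosen after seeing the data, so these values do not decide the matter. No biological explanation was tested, since both replicates carry the same labels.

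The 10th percentile of X scores lay above the highest of the 4 large autosomal arms by 14.0 SDs of those arms in replicate 1 and by 5.29 in replicate 2. Wider clusters on X are argued against, since X clusters scored higher in 10 of 10 width classes in both replicates, by a median of 0.096 in replicate 1 and 0.19 in replicate 2. A stricter effective threshold on X, as fewer reads from a single male X might give, stays open: the 90th percentile exceeded the highest autosomal arm by 5.53 SDs in replicate 2 but by 0.0036 SDs in replicate 1. Clusters per Mb did not settle this either, with 56.2 on X against 52.0 on the large autosomal arms in replicate 1, and 78.1 against 86.9 in replicate 2. Dosage compensation was not tested, since the labels do not part the sexes.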
